A study of Drosophila melanogaster with 4 samples.

How the data were processed

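Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on Drosophila melanogaster embryos with a rabbit polyclonal antibody raised against part of the CG16778 protein. Per the labels, the series holds 4 libraries, of which 2 are ChIP libraries (replicates 1 and 2) and 2 are input DNA libraries (replicates 1 and 2). The strain is the y; cn bw sp stock and the sex of the embryos is given as unknown. Per the labels, the stage is 0 to 8 h, whereas the collection step in the labels' protocols speaks of an egg laying of 8 to 16 h. The protocol describes fresh plates after a pre-laying period of 2 h, an egg laying of 8 h, fixation in 1.8% formaldehyde for 15 min, chromatin from 150 mg of material and an antibody incubation of 4 h.

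The deposited file used here is 1 peak list for the whole series, with a sequence name, a start, an end and 1 score per peak. Per the file headers, the coordinates are those of FlyBase release 5 of the genome, and the source column names MACS as the peak caller. The submitters' processing notes name CASAVA 1.7.0.2 and 1.7.0.3, BWA, MACS2 and the build BDGP5. The thresholds, the versions of BWA and MACS2, the way ChIP and input libraries entered the call, and whether replicates were pooled are not given in the sources used here. No library has values of its own in the list, so replicates could not be compared, no read depth was known, and the contrast of ChIP with input was the one made by the authors' caller.

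The deposited score column carries no unit. The 2 scales considered were a fold enrichment and a −log10 p-value. Many peaks shared scores that formed a ladder. The ladder fitted was −log10 of the Poisson upper tail at consecutive whole pileups over a single background of 35.427 fragments. Each of its 27 steps between 7.02 and 16.89 had an observed score within 0.00482. These scores held 697 peaks, and the sparsest held 1. Scores with 2 decimals lie densely there, so this closeness alone decides nothing. The widening of these steps from 0.32 to 0.44 follows from the fit and does not tell the 2 scales apart. A peak was counted as on a step if its score lay within 0.0075 of it. In a search of backgrounds between 5 and 80, this background took in 24.6% of the scores up to 20, and the best background more than 0.5 away took in 10.4%. Of the whole list, 24.8% lay on the steps, against 3.77% on a ladder shifted to lie midway between them. The deposited scores were therefore read as −log10 p-values by the authors' caller, a reading that rests on the values alone, and were used only to describe and rank peaks within the list. Peak positions were used as deposited, counted from 1, and the peak centre was the midpoint, since the list gives no summit.

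Only the gene table of genome release 6 was at hand, and it was used for the name of the target gene alone. Peaks in release 5 coordinates were not assigned to genes, promoters or sequence words, so the promoter overlap, the annotation classes, the strength by location, the 21 gene lists and the 21 sequence words that had been fixed before the data were examined were not run. In that case the rule set before the data were examined was to name the 10 peaks with the highest scores by their coordinates. Groups of peaks and bins named in addition were chosen after their values were seen.

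Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9. The major arms were 2L, 2R, 3L, 3R, 4 and X. Shares of peaks per arm were given with exact 95% Clopper-Pearson intervals, which cover counting error only. Density was counted by peak centre in full 1-Mb bins of the 5 long arms, and each arm was compared with the other long arms by a two-sided permutation test of bin means with 100000 resamples and Benjamini-Hochberg adjustment over the 5 arms. This density test was added after the list had been seen, because the planned exact binomial test needed arm lengths of release 5. A version of that test against the length between the first and last peak of each arm was also run. Spacing was the median distance between neighbouring peak centres, set against 1000 uniform random placements of the same number of peaks between the first and last peak of each arm, two-sided, so that the smallest p it can give is 0.002. Width and score were related across peaks by Pearson's r and Spearman's rank correlation with 100000 permutations. Peaks are not biological replicates, so every p-value describes this list and not the spread between embryo collections.

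The functions were tested on simulated data with 4004 peaks on the 6 arms or with 114 bins. The spacing test called 1 of 40 uniform sets and 40 of 40 sets in which 30 percent of peaks had been moved next to another peak. The density test called 2 of 40 sets with equal rates and 40 of 40 sets with X at 0.6 of the rate. The background of a simulated score ladder was recovered within 0.02 in 10 of 10 sets. The alternatives tried were the peaks above the median score, the major arms alone, merging of peaks within 500 or 5000 bp, bins of 500 kb, placement inside 1-Mb bins, each arm left out, and, for unplaced sequence, a matched width range and Uextra alone.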

Results

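CG16778, listed under the symbol lov in the current gene table, is a protein-coding Drosophila gene for a BTB/POZ-domain protein, a class of proteins that includes many DNA-binding regulators. Its binding in whole embryos of 0 to 8 h was mapped by ChIP-seq with 2 ChIP and 2 input libraries. The question addressed was where in the genome the protein is found at this stage. The deposited result used here was a single list of 4164 peaks for the series, so every value below belongs to the list as a whole and carries no replicate error. The read depth of the libraries is unknown from the list.

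The 4164 peaks covered 1912 kb in all. Peak widths ran from 201 to 3679 bp with a median of 356 bp (quartiles 258 and 542 bp), and 263 peaks (6.32%) were wider than 1000 bp. The authors' scores, read as −log10 p-values, ran from 6.38 to 289.64 with a median of 12.33 (quartiles 9.91 and 16.45). Most of the list was of low score, since 84.5% of the peaks lay under 20. Only 62 peaks exceeded 50 and 13 exceeded 100.

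Of the 10 peaks with the highest scores, 8 lay on the arms of chromosomes 2 and 3 and 2 on sequence outside the arms. The score was read as the caller's −log10 p-value, which is not a measure of binding strength. On that reading, scores on X were mostly set against the genome-wide background (81.3% of X peaks, against 16.3% on 2L, 2R, 3L and 3R), so ranks on X and on the other arms are not directly comparable. The peak with the highest score lay on 3R at 21856120 to 21857935 (release 5), was 1816 bp wide and scored 289.64, which is 23.5 times the median of the list. It was followed by a peak on 3L at 5967798 to 5970974, which scored 241.38 and, at 3177 bp, was also the second widest of the list. A peak on 2L at 8415798 to 8417272 scored 220.15, and one on 3L at 7904055 to 7906389 scored 218.91. The peak on 2L at 3152452 to 3153781 scored 189.5, and the peak on 2R at 8915393 to 8916544 scored 183.53. The last arm peaks among these 10 lay on 2L at 1556662 to 1557351, with a score of 156.72, and on 3L at 10764628 to 10765649, with a score of 129.94. The other 2 of the 10 lay on sequence that release 5 does not place on an arm, namely Uextra at 22939350 to 22939798 (123.06) and U at 2605840 to 2606292 (111.26). None of the 10 lay on X, where the highest score was 82.61, or on chromosome 4, where it was 33.35. The genes at these sites were not analysed here.

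The 3R peak had 11 other peaks within 10 kb, of which the highest scored 78.04. The highest-scoring 3L peak had 9 others within 10 kb, none above 16.55. The peak on 2L at 1556662 to 1557351 had no other peak within 10 kb.

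Of the 4164 peaks, 4004 (96.2%) lay on the major arms and 160 on other sequences. Arm 3R held 1013 peaks, 3L held 855, 2R held 853 and 2L held 760, whereas X held 498 and chromosome 4 held 25. X thus had 12.4% of the major-arm peaks (exact 95% interval 11.4 to 13.5%). Chromosome 4 had 0.624% (0.404 to 0.92%), so its density was known only roughly.

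Peaks were sparser on X than on the other long arms. X held 23.3 ± 8.83 peaks per Mb (mean ± SD over 21 bins of 1 Mb), against 36.9 ± 13.7 over the 93 bins of 2L, 2R, 3L and 3R. The ratio was 0.632, and the difference (X minus the others) of −13.6 peaks per Mb was larger than the bins' spread allowed under two-sided permutation (p = 5.00e-05, adjusted p = 0.00025 over 5 arms). Among the peaks above the median score alone the ratio was 0.596 (permutation p = 2.00e-05). Above scores of 10, 15, 20 and 30 it was 0.623, 0.563, 0.596 and 0.532, values that were not tested. The score ladder also separated X from the other arms, as 81.3% of X peaks but 16.3% of the peaks on 2L, 2R, 3L and 3R had scores on the steps of the genome-wide background. Arm 2R had the highest mean, 40.5 ± 15.0 peaks per Mb over 21 bins against 33.0 over the other long arms, and this difference did not pass after adjustment (permutation test, p = 0.026, adjusted p = 0.0649). For 2L (34.1 ± 16.0, adjusted p = 0.915), 3L (37.1 ± 11.7, adjusted p = 0.499) and 3R (36.2 ± 12.2, adjusted p = 0.56) the permutation test found no difference that passed the threshold. An exact binomial test of each arm's share of peaks against its share of the length between first and last peaks also called X (adjusted p = 3.64e-24), and it called 2R (2.00e-07), 3L (0.0113) and 3R (0.0288) as higher. In that test the low share on X by itself raises the shares of the other arms. The bin means of 3L (37.1) and 3R (36.2) lay near the 36.9 of 2L, 2R, 3L and 3R together. The test also counts every peak as independent, which the grouping of peaks described next does not bear out, so the comparison of bins was taken as the result.

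Every one of the 114 bins contained peaks, from 3 to 80 with a median of 34. The densest bin was 2L from 21000001 to 22000000, with 80 peaks, followed by 2R from 9000001 to 10000000 with 68. Next came the first megabase of 3R with 67 and the first megabase of 3L with 62. In the 2L bin, 30 of the peaks lay within 53.5 kb (21463929 to 21517393) and 11 within 23.6 kb (21417050 to 21440669). Its count was thus not spread evenly over the megabase. The first 2 bins of 2R held a mean of 8.0 peaks, against 45.4 in the middle of that arm.

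**Figure D1:**
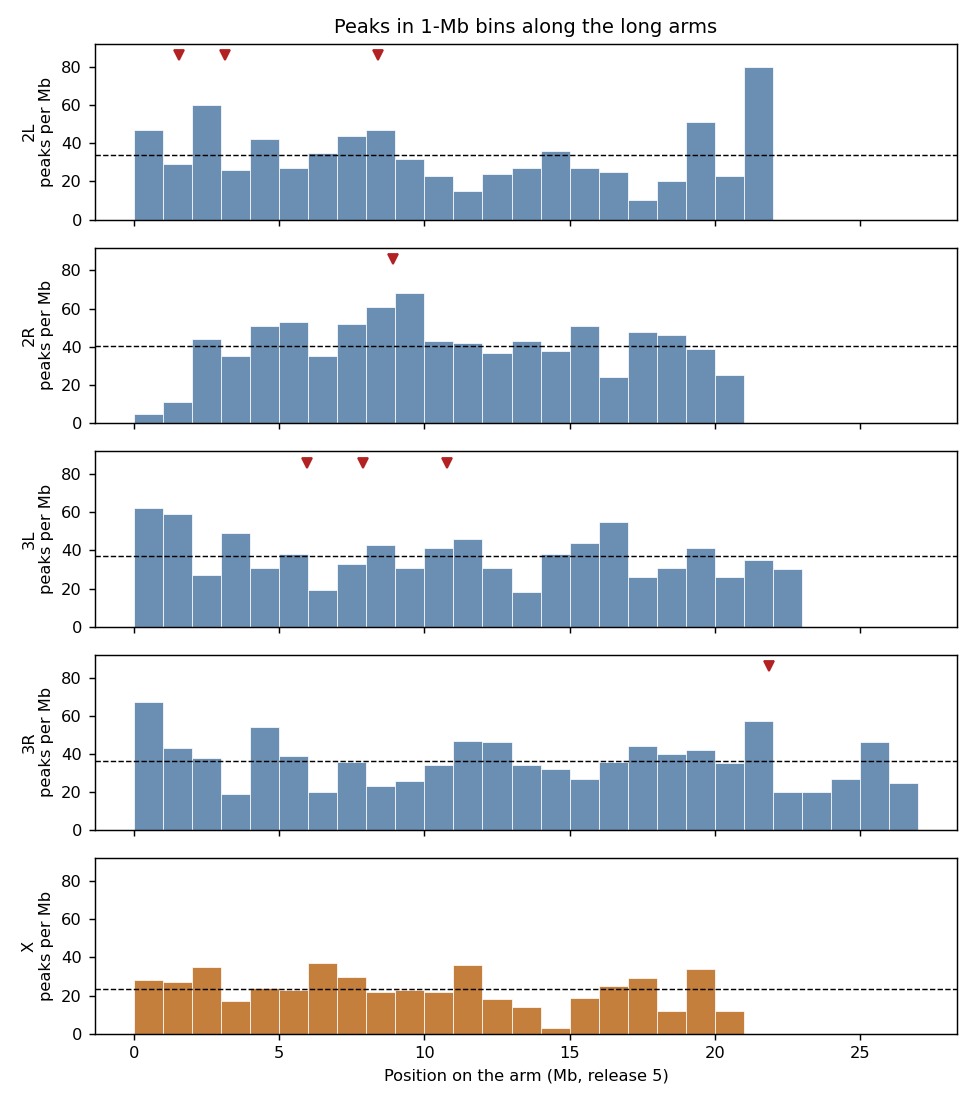
Number of peaks (vertical axis, peaks per Mb) in each full 1-Mb bin along the 5 long arms (horizontal axis, Mb in release 5 coordinates). Dashed lines give each arm's mean and red triangles mark the 8 arm peaks among the 10 with the highest scores. The mean on X is 23.3 peaks per Mb, and 2L has a bin of 80.

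Within the arms, peaks lay in groups. The median distance between neighbouring peak centres was 5794.5 bp, whereas 1000 random placements gave 19996 ± 319 bp (mean ± SD) and never fell under 19060 bp. The ratio was 0.29 (two-sided permutation test by random placement, p = 0.002, the smallest value the placements can give). All 6 arms showed it, from a ratio of 0.25 on 2L to 0.346 on chromosome 4 (same permutation test, adjusted p = 0.002 on each). Of the neighbouring pairs, 22.2% were at most 1000 bp apart against 3.43% in random placements, and 48.3% were at most 5000 bp apart against 16.0%. At 50000 bp the observed share, 83.2%, lay within the random range of 80.8 to 83.4%. Random positions may fall in sequence that reads cannot be aligned to, which was not masked.

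**Figure D2:**
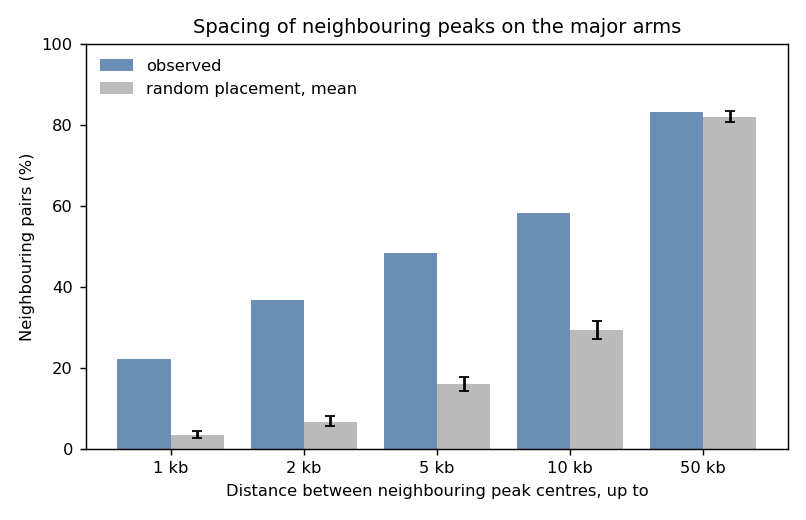
Share of neighbouring peak pairs on the major arms (vertical axis, percent) whose centres lie within each distance (horizontal axis). Blue bars are observed, grey bars are the mean of 1000 random placements, and error bars run from the lowest to the highest placement. The observed share lies above every placement at 1 kb (22.2% against a mean of 3.43%) and within the range of the placements at 50 kb.

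Joining peaks with gaps of up to 5 kb left 1128 single peaks, 454 pairs and 452 groups of 3 or more, and these larger groups held 1968 peaks (49.2% of the major-arm peaks). Random placements also form some such groups, and the share they give was not computed. There were 16 groups of 10 or more peaks. The largest group held 31 peaks in 46.5 kb on 3R from 21822268 to 21868760 and contained the highest-scoring peak of the list. The second held 30 peaks in 53.5 kb on 2L from 21463929 to 21517393, where the highest score was 16.61. The third held 17 peaks on 3R from 12056595 to 12081144, with a highest score of 22.77, and the fourth held 16 on 3L from 14951621 to 14976527, with a highest score of 19.14. On X the largest group held 12 peaks, from 2186817 to 2201312. Merging of peaks within 500 bp, which joins fragments of a broad region that lie this close, moved the spacing ratio to 0.462, and merging within 5000 bp moved it to 0.747. Among the peaks above the median score alone it was 0.501. The permutation p was 0.002 in each case.

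Peaks with higher scores were wider. Across the 4164 peaks, width and score had a Spearman correlation of 0.639 and a Pearson r of 0.529 (permutation test, p = 1e-05 for each, the smallest the permutations can give). Without the 2 peaks farthest from the median width, r was 0.515. The median width was 259 bp in the lowest of 4 equal classes by score, 305 and 394 bp in the next classes, and 646 bp in the highest. Peaks are not independent replicates, and both measures come from the same pileup.

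**Figure D3:**
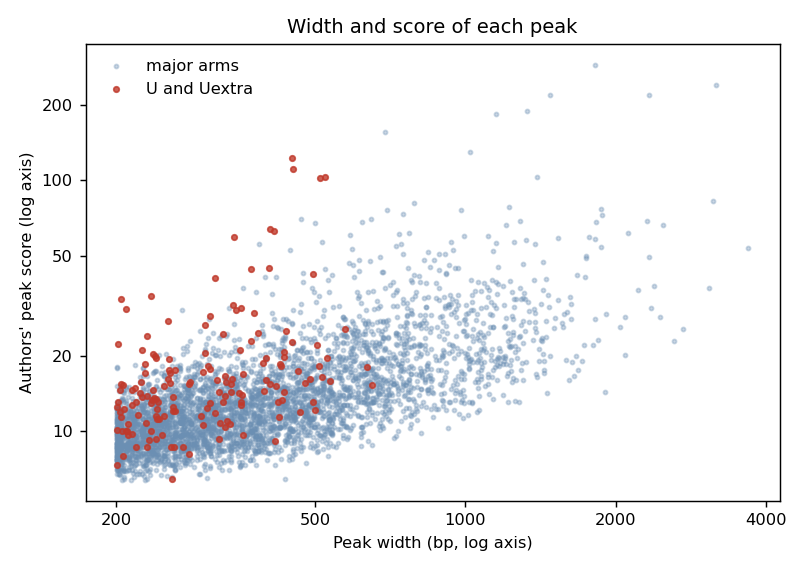
Each point is a peak, with its width in bp (horizontal log axis) and the authors' score (vertical log axis). Blue points lie on the major arms and red points on U and Uextra. Scores rise with width (Spearman correlation 0.639), and red points reach high scores at widths of at most 651 bp.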

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

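The tests in this part were chosen after the list had been seen. The list held 148 peaks on Uextra and 7 on U, which gather sequence that release 5 does not place on an arm, and they were singled out because they lie outside the arms that the comparisons use and exceed the limit of 3 that a count of 0 allows. These 155 peaks had a higher median score than the 4004 peaks of the major arms, 14.9 against 12.3 (difference 2.62, bootstrap 95% interval 1.46 to 3.48, permutation test, p = 1e-05, the smallest the permutations can give). They were narrower, with a median of 301 against 361 bp (difference −60 bp, interval −104 to −35 bp, permutation p = 0.00752). They supplied 7 of the 42 peaks in the top 1% by score, that is 4.52% of the unplaced peaks against 0.874% of the arm peaks.

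A technical explanation for the unplaced peaks is repeated sequence in which collapsed copies raise reads in the control as well. If the local control were raised, fewer of these peaks should be scored against the genome-wide background, and the reverse was found: 35.5% of them lay on its steps against 24.4% on the arms, a difference of 11.1 percentage points (95% interval 3.91 to 19.0). Against 2L, 2R, 3L and 3R alone the difference was 19.2 points. A local control above the genome-wide background at all of these peaks is thus argued against. The share does not tell how far the control was raised at the peaks off the steps. A raised control at part of the unplaced peaks therefore stays open. Whether the control was raised at the highest-scoring of them was not examined. Repeats that are enriched in the ChIP alone, or reads placed at random among copies, stay open. No biological explanation was tested, since the sequence of these sites was not analysed here.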

How the results depend on the processing

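Of 43 comparisons of a result with an alternative setting, 37 kept their direction and their side of the threshold or moved by less than 1 SD over peaks (medians), the 95% interval (shares) or a factor of 1.5 (counts and covered length), and none reversed. These limits are unequal: above the median score, the median width went from 356 to 502 bp and the median score from 12.33 to 16.45, as the selection implies, and both stayed within the wide SD over peaks (309 bp and 12.4). In 3 of the others the exact binomial test against arm spans, which counts every peak as independent, called arms that the bins did not: the ratio of peak share to length share was 1.19 on 2R, 1.09 on 3L and 1.07 on 3R. The low share on X by itself raises such ratios on the other arms. The last 3 came from taking only the peaks above the median score, which by construction left 2081 peaks and 1253.7 kb of covered length, and which placed 22.7% of the arm peaks on 2R against 21.3% in the full list, and the cause of that last shift was not tested. The spacing ratio of 0.29 stayed below 1 under every alternative: 0.501 above the median score, 0.462 and 0.747 after merging within 500 and 5000 bp, 0.313 with placement inside 1-Mb bins, and 0.28 to 0.299 with each arm left out in turn. The X ratio lay between 0.596 and 0.745 under 4 alternatives (permutation p at most 0.00075) and was 0.673 against arm spans. The correlation of width with score was 0.66 on the major arms and 0.512 above the median score. The score difference of unplaced peaks was 3.53 within a matched width range, which does not match peaks 1 by 1, and 2.74 for Uextra alone. Leaving out bins without a peak was not run, because every bin had one. The alternatives listed for promoters, annotation classes, gene lists, sequence words and strength by location were not run, because no annotation of release 5 was used here. No paired analysis was possible because the list has no values per library, and for the same reason no replicate could be left out. The scores are the only measure of depth in the list, so weak sites below the caller's threshold, and any site seen in 1 replicate only, cannot be judged.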

Other observations

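The tests in this part were not in the plan made before the list was seen, except for the spacing after merging within 500 bp, and each explanation is a hypothesis.

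The median score in the 10 largest groups of peaks ran from 10.5 to 14.0, against 12.33 in the whole list, and differences between groups were not tested. The 30 peaks on 2L from 21463929 to 21517393 had scores between 7.84 and 16.61 with a median of 10.5 and a median width of 295 bp. The 31 peaks on 3R from 21822268 to 21868760 ran from 6.95 to 289.64 with a median of 12.7.

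The 403 peaks in the top 10% by score on the arms (23.59 or more) had 2.16 ± 2.20 other peaks within 10 kb (mean ± SD), against 2.64 ± 2.58 for the 3601 others, a difference of −0.477 (permutation test, p = 0.00038). This direction is the reverse of that predicted if higher-scoring peaks lay in denser parts of the arms. The permutations here count every peak or pair as independent, which the grouping of peaks does not bear out. Their p-values may therefore be too small, and the difference was not taken to decide the question. Higher-scoring peaks are also wider, and a wide peak may take in sites that would otherwise be listed as neighbours, which was not tested. Scores of neighbouring peaks more than 2000 bp apart had no correlation that passed the test across 2526 pairs (Spearman correlation 0.0257, permutation p = 0.196). Over 4 distance ranges, the Spearman correlation was 0.0547 in the 1472 pairs up to 2000 bp apart (permutation, adjusted p = 0.0705), 0.0981 in the 861 pairs from 2000 to 10000 bp (0.0156), −0.0107 in the 993 pairs from 10000 to 50000 bp (0.83) and −0.00831 in the 672 pairs farther apart (0.83). Only the second range passed, with a small value, and the closest pairs did not.

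The lower density of peaks on X may reflect fewer reads on X. If X had fewer control reads, its peaks should more often be scored against the genome-wide background, which a MACS caller uses where the local control lies below it. This was found: 405 of 498 X peaks lay on the steps of that background against 568 of 3481 on 2L, 2R, 3L and 3R, a difference of 65.0 percentage points (95% interval 61.1 to 68.4). With the ladder shifted to lie midway between its steps, only 1.41% of the X peaks matched. An unsexed collection with males, which carry a single X, is a candidate source of fewer X reads and could give this value. Chromosome 4, an autosome, had 2 of 25 peaks on the steps. High shares also occurred outside the major arms, though in small counts. On the steps lay 3 of 3 peaks on 2RHet, 1 of 1 on 3LHet and 5 of 7 on U, and 50 of 148 on Uextra. With fewer reads and an unchanged background floor the same enrichment gives a lower score, so the X ratio of 0.632 cannot be read as a lower number of binding sites, and a real difference in binding stays open and untested.

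The grouping of peaks was set against 2 technical explanations. Splitting of single broad regions into fragments up to 500 bp apart is argued against as the whole cause, because the spacing ratio was still 0.462 after such peaks were merged (permutation p = 0.002). Merging within 5000 bp moved the ratio to 0.747 (permutation p = 0.002). Broad regions split by gaps wider than 500 bp were not told apart from groups of separate sites. Unequal density at the scale of 1 Mb is likewise argued against as the whole cause, with a ratio of 0.313 when peaks were placed at random inside their own 1-Mb bins (permutation p = 0.002). Accessible chromatin that comes in groups, and regulatory regions with several bound sites, may both give a ratio such as 0.462 and stay open. The sequence within the groups was not analysed here, so a site repeated over copies is not told apart from separate sites.

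On the reading of the score as a Poisson p-value, a pileup can be matched to the 1034 peaks on the steps of the genome-wide background. These were 24.8% of the list, against 3.77% that matched a ladder shifted to lie midway between the steps. Of the 1034 peaks, 405 (39.2%) lie on X. The folds are over the floor of the caller, which is at or above the local control at these peaks, and so are no measure of enrichment over that control. The lowest of them, with a score of 6.42, corresponds to a pileup of 68 fragments over a background of 35.427, or 1.92-fold over that floor. Their median score of 11.92 corresponds to 84 fragments, or 2.37-fold, on X and on the other sequences taken separately. The highest score counted as on a step, 156.72, would correspond to 290 fragments, or 8.19-fold. It lies far above the scores on which the background was chosen. This match was not told apart from chance, so no pileup is taken as known for that peak.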
